A study of Mus musculus with 14 samples.

How the data were processed

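Total RNA from the cortex of 14 mice of the C57BL/6J strain, 8 weeks old, was measured by RNA sequencing. Per the labels, 7 animals were heterozygous for a knockout of Dnmt3a, a gene that encodes a DNA methyltransferase, and 7 were wild-type littermates. Each genotype held 4 females and 3 males. Genotype and sex were taken from the labels of each sample, and replicates are numbered in the order of the series within each genotype. Per the labels' protocols, libraries were made with a directional kit and sequenced as single-end reads.

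The authors deposited one table of gene symbols for the whole series, and the 14 sample columns hold whole-number counts of reads per gene with no normalization. Trim Galore, Bowtie, STAR and bedtools are named in the submitters' processing notes without versions or roles, and the notes name the mm9 build. Whether the counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands could be mixed. The deposited table also holds 4 columns of the authors' own comparison of genotypes: a log2 fold change, a test statistic with no fixed range (a score), a p-value and an adjusted p-value. The deposited log2 fold changes are shrunken towards 0. DESeq2 with a prior on the fold change, a term for sex and a term that separates 2 sets of title prefixes gave values within 1e-06 of the deposited log2 fold changes over all genes with reads, whereas a design with sex alone differed by up to 0.13. This identifies the scale and the terms of those columns from the values.

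The table lists 34193 gene symbols, of which 14540 have no read in any animal. Total counts ranged from 8951835 to 14335406 per animal. With filterByExpr by genotype, 13815 genes were tested, and these held 99.9% of all counts. Counts were analysed with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by the quasi-likelihood F test with TMM factors and robust dispersion, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparison of genotypes had sex as an additive term. Contrasts within each sex and their difference came from a fit of the 4 groups of genotype and sex, and the comparison of females with males had genotype as a term. CPM values are edgeR's cpm, computed with TMM-scaled library sizes. Standard errors of log2 fold changes were computed from the fold change and the F statistic.

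The 32 gene lists were fixed before the data were examined, among them markers of other cell types and of neighbouring tissue, and were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Mean log2 CPM of each list (prior count 2) was also compared by two-sided exact permutation of genotype labels within the title prefix (192 relabellings) and within sex (1400 relabellings). Agreement between the sexes was Pearson's r across genes of the female and male differences of mean log2 CPM, and long genes were genes over 100 kb. Both had two-sided exact permutation tests of genotype within sex. Gene lengths and chromosomes came from GENCODE M21, matched by symbol, with 28376 symbols found directly, 2532 through an older name and 3285 without a match. Of the tested genes, 98.5% had a length. That annotation is of another build than the counts, so no coordinates are given.

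Sample titles share a leading number between animals of both genotypes, and these 6 title prefixes each hold animals of 1 sex. Across genes, the deviations from the genotype means of heterozygous and wild-type animals of the same prefix correlated at 0.2 to 0.517 in the 9 pairs, so a fit with the prefix as a block in place of sex is given beside the results it changes. The rule was a correlation above 0.1 in every pair, and the calls of the fit with the block had already been seen when it was applied. The labels do not say what the prefix marks. Animals of 1 prefix share sex and set, so correlations above 0.1 could come from these alone and do not test the prefix. With sex and the 2 sets of prefixes also removed, all 9 correlations were negative (-0.328 to -0.00545). For prefixes 119 and 141, each the only one of its sex in its set, these terms remove most of what a prefix shares. There the prefix is not separated from sex and set. In the other set each sex holds more than 1 prefix. Its pairs gave -0.18 to -0.00545, so no shared prefix effect beyond sex and set was seen there. The first principal component of log2 CPM (34.3% of the variance) separated 6 animals of prefixes 119 and 141, called set B here, from 8 animals of prefixes 046, 047, 048 and 139, called set A. The sets were named after this was seen, and a term with these sets gives the deposited fold changes. Each set holds equal numbers of both genotypes. Log2 fold changes and list medians of each set come from a fit of all 14 animals with sex, set and a genotype term within each set, while counts of genes and p-values within a set come from a fit of its animals alone.

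Genes were named by a rule fixed before the data were examined. It takes Dnmt3a, up to 12 genes per direction with the smallest p past the threshold by genotype and, where fewer pass, the next by p up to 5 as values, and up to 4 members per list by p. In each sex and for their difference it takes up to 8 genes per direction past the threshold, or the 3 with the smallest p as values. It also takes the sex-linked genes with up to 10 others for sex, and the 5 genes over 100 kb with the smallest p. The genes 2410018M08Rik, 9130019O22Rik and Gm15645, which the rule also takes, were passed over, as were its other genes for sex that did not pass. Genes with a mean count under 20 are named only as uncertain. Genes called only with the block were named after their values were seen.

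Alternatives were RLE and upper-quartile factors, no filter and a stricter filter, each animal left out, DESeq2 1.42.0, limma-voom, no sex term, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, and other length limits. Terms for the set, each set alone, and a filter by sex were added after the data were seen. The procedures were tested on simulated counts drawn for the 13815 genes from the means and library sizes of these samples, with 50 genes changed at each of 4 fold sizes. For genotype in all animals, 24% of genes changed by 1.25-fold, 72% changed by 1.5-fold and 100% changed by 2-fold were recovered, and 14 of the 162 calls were unchanged genes. With the block 16 of 159 calls were unchanged genes. Both shares are above the threshold of 0.05. For the contrast in males, 38% of genes changed by 1.5-fold and 92% changed by 2-fold were recovered. The simulated spread is independent between genes and lacks the shared shifts of the real libraries. More genes passed than in the data, which makes the adjusted threshold more lenient, so the shares recovered can overstate those for the data. No 2 libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over the 91 pairs was 2.82.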

Results

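RNA from the cortex of 7 heterozygous Dnmt3a knockout mice and 7 wild-type littermates was compared, with 4 females and 3 males in each genotype. Total counts per animal lay between 9794201 and 14206585 in wild-type mice and between 8951835 and 14335406 in heterozygotes. The animals fell into 2 sets by the leading number of the sample title. Set A held 8 animals and set B held 6, with both genotypes equally represented in each. The sets were defined from these prefixes after the data were seen, and the labels do not name them.

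**Figure D1:**
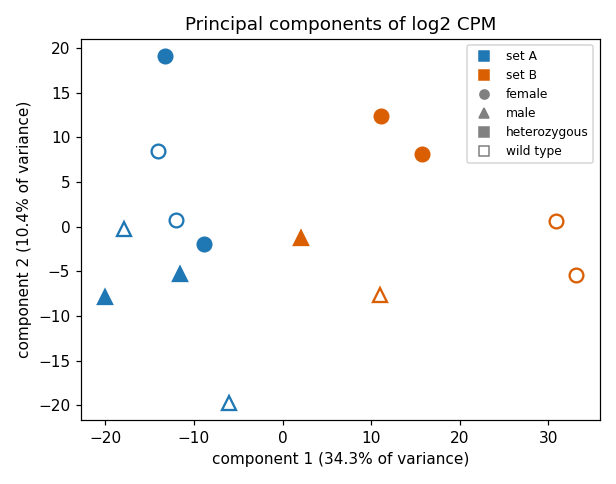
Each point is 1 animal, placed by its scores on the first (34.3% of the variance) and second (10.4%) principal components of log2 CPM, with colour for the set, shape for the sex and filling for the genotype. Set B lies at 2.06 or above on the first component and set A at -6.08 or below.

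Mitochondrial transcripts other than the ribosomal RNAs took 0.697% ± 0.105 of counts in set A (SD, n = 8) and 1.60% ± 0.334 in set B (SD, n = 6). Within set B they took 1.82% ± 0.270 in wild-type animals and 1.37% ± 0.234 in heterozygotes (SD, n = 3 each), while in set A they took 0.699% ± 0.136 and 0.695% ± 0.0835 (SD, n = 4 each). Ribosomal protein genes took 0.259% ± 0.0290 of counts in wild-type and 0.210% ± 0.0160 in heterozygous animals of set B (SD, n = 3 each), and 0.182% ± 0.0155 and 0.181% ± 0.00842 in set A (SD, n = 4 each).

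The targeted gene was examined first. Dnmt3a, which encodes a de novo DNA methyltransferase, was at 146 ± 14.2 CPM in wild-type cortex (SD, n = 7) and 99.0 ± 11.4 CPM in heterozygous cortex (SD, n = 7). The ranges did not overlap, with 124 to 164 CPM in wild-type and 84.3 to 118 CPM in heterozygous animals. The fitted level in heterozygotes was 67.6% of wild type (95% interval 60.6 to 75.4). The log2 fold change was -0.57 (SE 0.0752, adjusted p = 0.00774 by edgeR's quasi-likelihood test). A two-sided exact permutation test over the 3432 splits of the animals gave p = 0.000583, the smallest it can give. The change was -0.56 in set A and -0.58 in set B, and the 8 animals of set A alone did not pass the threshold (adjusted p = 0.111 by the same test). Counts were summed over the whole gene, so transcripts of the knockout allele could be included.

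Across the 13815 genes tested, 2 differed by genotype, Dnmt3a downward and Gpnmb upward. Gpnmb, which encodes a transmembrane glycoprotein known from microglia and macrophages, rose from 1.80 ± 0.801 to 4.62 ± 0.453 CPM (SD, n = 7 each). Its log2 fold change was 1.32 (SE 0.211, adjusted p = 0.0454 by edgeR), with 1.16 in set A and 1.61 in set B, and every heterozygote lay above every wild-type animal. Myh7b, a myosin heavy chain gene, had a log2 fold change of 0.81 (SE 0.137) and did not pass (adjusted p = 0.0627 by edgeR). The next values upward were 0.53 for Gm16882, 1.08 for Mab21l1 and 0.40 for Ppm1m, and downward -0.54 for Cartpt, which encodes a neuropeptide precursor, and -0.54 for Aldh1a1, a retinaldehyde dehydrogenase gene. Dok1 (-0.84) and Gm17251 (-0.64) had mean counts under 20 and are uncertain. None of these passed the threshold in this fit. The Gpnmb call was lost without wild type replicate 5, 6 or 7 or without any single heterozygote, with adjusted p by edgeR between 0.0545 and 0.188 and log2 fold changes between 1.24 and 1.36.

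**Figure D2:**
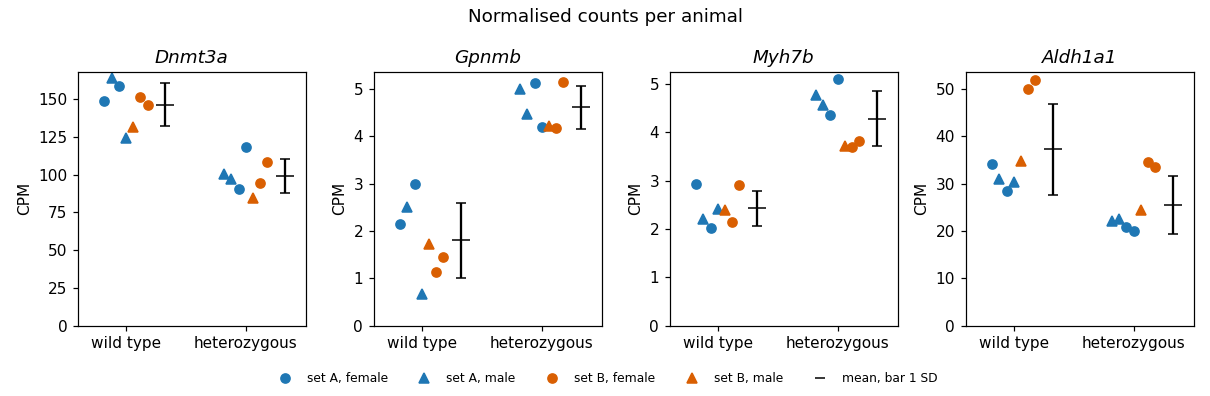
CPM of Dnmt3a, Gpnmb, Myh7b and Aldh1a1 in each animal, by genotype, with colour for the set, shape for the sex, and the mean and 1 SD beside the points. Dnmt3a ranged from 124 to 164 CPM in wild-type and 84.3 to 118 CPM in heterozygous animals, and Aldh1a1 lay higher in set B than in set A in both genotypes.

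With the title prefix as a block in place of sex, 56 genes differed by genotype, 36 higher and 20 lower, and both genes called without the block were among them. Aldh1a1 fell by 0.55 on the log2 scale (SE 0.0544, adjusted p = 4.23e-06 by edgeR with the block), and Dnmt3a fell by 0.57 (SE 0.0545). Among the genes that rose in this fit were Chrna4, a nicotinic acetylcholine receptor subunit gene (0.36), Dkk3, which encodes a secreted protein of the Dickkopf family (0.32), Klf10, a zinc finger transcription factor gene (0.48), Ntn5 (0.61), Gfra2, a co-receptor gene of the GDNF family (0.28), and Wnt10a, a WNT ligand gene (0.47). Genes that fell included Amotl1 (-0.28), Ranbp3l (-0.69), Amz1 (-0.48), Myoc (-0.38) and Agt, the angiotensinogen gene (-0.52). Rec8 and Cdcp1 were also called but had mean counts under 20 and are uncertain. A term for the set added to sex gave 15 genes, 12 higher and 3 lower, and all 15 were among the 56. Gpnmb, Myh7b, Gm16882, Mab21l1 and Ppm1m, all higher, passed in both of these fits. Their adjusted p by edgeR was 0.00205, 0.0157, 0.00394, 0.0173 and 0.0173 with the block. With the set term it was 0.00158, 0.0175, 0.0175, 0.0309 and 0.0277 by edgeR.

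The authors' deposited table gave 27 genes with an adjusted p under 0.05, 20 higher and 7 lower in heterozygotes. Its strongest values were -0.45 for Dnmt3a, 0.44 for Gpnmb and -0.39 for Aldh1a1, as shrunken log2 fold changes in the authors' deposited table. Of those 27 genes, 24 were among the 56 called with the block, Myh7b, Gm16882, Mab21l1 and Ppm1m among them. Klf10, Ranbp3l, Myoc, Agt and Cdcp1, named above, did not pass in the authors' DESeq comparison (adjusted p = 0.158, 0.0554, 0.269, 0.24 and 0.0707). Nor did Ier5, Egr1, Sulf2, Unc13c, Filip1 and Ndn, named below with the block (adjusted p from 0.0862 to 0.72). The set term called none of these, since the authors' comparison also called all of its 15 genes.

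Gene groups fixed before the data were examined were compared next. With the preset correlation, camera called 11 of the 32 lists, 4 higher and 7 lower, and with an estimated correlation it called none, the smallest adjusted p being 0.79. No member of a called list passed over all genes in the fit without the block, or when adjusted over the list alone. Outside the called lists, Dnmt3a passed in its own list, and Ttr (-0.92, mean count under 20 and so uncertain) passed among choroid plexus markers adjusted over the list alone. Within the title prefix, exact permutation of the list means gave no adjusted p under 0.368. The smallest p that it can give is 0.01, so 1 list alone could not pass over the 32 lists. Within sex, where smaller p values are possible, exact permutation gave no adjusted p under 0.702. Relabellings within sex do not keep the sets balanced between genotypes, so level differences between the sets can widen their spread and weaken that test. The estimated correlation between genes of the 11 called lists lay between 0.15 (endothelial cells and pericytes) and 0.86 (astrocytes), above the preset 0.01. It was 0.58 for ribosomal protein genes and 0.57 for immediate early genes. The small p-values of the preset test below, also those within a set, therefore overstate the evidence. The directions below are those of the camera test alone. Within each set, camera with an estimated correlation also called none (smallest adjusted p = 0.45 in set A and 0.39 in set B).

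Immediate early genes, transcription factors and effectors induced by neuronal activity, were higher in heterozygotes. Of 26 measured, 23 had a positive value, with a median log2 fold change of 0.24 (camera adjusted p = 5.32e-05, and adjusted p = 0.793 with an estimated correlation). Examples were Egr3 at 0.23, Ier5 at 0.27 and Nptx2 at 0.24, none of which passed alone. With the block, Ier5 (0.28) and Egr1 (0.28) passed over all genes and 8 members passed adjusted over the list alone. The median was 0.22 in set A (camera adjusted p = 1.19e-07) and 0.18 in set B (camera adjusted p = 9.72e-05).

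Markers of oligodendrocytes, the myelin-forming cells, were higher, with 17 of 22 positive and a median of 0.16 (camera adjusted p = 1.56e-06, and adjusted p = 0.793 with an estimated correlation). Trf had 0.27, Cnp 0.19 and Cldn11 0.20, and none passed alone. With the block, 9 members passed adjusted over the list alone. The median was 0.094 in set A (camera adjusted p = 0.00247) and 0.22 in set B (camera adjusted p = 0.000107). Deep-layer neuron markers were also higher (13 of 17 positive, median 0.073, camera adjusted p = 0.00271, and adjusted p = 0.793 with an estimated correlation). Ntsr1 had 0.31 and Sulf2 0.25, and Sulf2 passed over all genes with the block (0.26). The median was 0.057 in set A and 0.099 in set B.

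Astrocyte markers were lower in heterozygotes, with 21 of 21 negative and a median of -0.19 (camera adjusted p = 1.56e-06, and adjusted p = 0.793 with an estimated correlation). Agt had -0.49, Gfap -0.40 and Clu -0.18, and none passed alone. With the block, Agt passed over all genes and 13 members passed adjusted over the list alone. The median was -0.012 in set A (camera adjusted p = 0.569) and -0.38 in set B (camera adjusted p = 2.78e-24). In set B, mitochondrial transcripts other than the ribosomal RNAs took 1.82% of counts in wild-type and 1.37% in heterozygous animals. Camera on the difference between the sets gave adjusted p = 3.67e-13 for this list, and none of the lists passed that comparison with an estimated correlation (smallest adjusted p = 0.25).

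Ribosomal protein genes followed the same split, with 58 of 60 negative and a median of -0.16 (camera adjusted p = 1.03e-09, and adjusted p = 0.793 with an estimated correlation), and medians of -0.022 in set A and -0.34 in set B. Rplp1 had -0.21 and Rpl8 -0.16, and neither passed. Genes of this family have many near-identical pseudogene copies, so single members are uncertain. Nuclear genes of oxidative phosphorylation were negative in 62 of 73, with a median of -0.078 (camera adjusted p = 0.000579, and adjusted p = 0.805 with an estimated correlation), and medians of 0.028 in set A and -0.23 in set B. Ndufa7 had -0.15 and Cox7a2 -0.19.

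Microglia markers were negative in 19 of 22 (median -0.096, camera adjusted p = 0.00177, and adjusted p = 0.805 with an estimated correlation), with Tyrobp at -0.48 and Tmem119 at -0.14, and medians of -0.0036 in set A, where the test pointed upward (adjusted p = 0.956), and -0.21 in set B. Markers of meninges and fibroblasts were negative in 14 of 18 (median -0.13, camera adjusted p = 0.00481, and adjusted p = 0.805 with an estimated correlation), with Dcn at -0.32 and Igfbp2 at -0.21, and medians of -0.053 in set A and -0.33 in set B. Markers of endothelial cells and pericytes were negative in 17 of 23 (median -0.11, camera adjusted p = 0.0036, and adjusted p = 0.793 with an estimated correlation), with Cldn5 at -0.20 and Slco1a4 at -0.16, and medians of -0.092 in set A and -0.11 in set B. Striatal markers were negative in 13 of 16 (median -0.095, camera adjusted p = 0.0297, and adjusted p = 0.814 with an estimated correlation), with Ecel1 at -0.67 and Gnal at -0.10, and medians of -0.19 in set A and 0.034 in set B, where the test pointed downward (adjusted p = 0.83).

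Autism risk genes were positive in 42 of 58, with a median of 0.0505 (camera adjusted p = 0.0297, and adjusted p = 0.805 with an estimated correlation). The members with the smallest p went the other way: Shank3, a postsynaptic scaffold gene, had -0.23 and Shank2 -0.20, and 2 members passed downward adjusted over the list alone with the block. In the authors' deposited DESeq comparison over all genes, Shank2 was lower (-0.17, adjusted p = 0.0109) and Shank3 did not pass (-0.18, adjusted p = 0.0862). The list's median was -0.0202 in set A and 0.13 in set B. With the block, camera also called presynaptic release genes (adjusted p = 0.0229, and adjusted p = 0.665 with an estimated correlation) and voltage-gated channels (adjusted p = 0.0229, and adjusted p = 0.742 with an estimated correlation), both higher, for 13 lists in all. The 1 presynaptic member past the threshold over all genes with the block, Unc13c, fell (-0.39). The other 21 lists had camera adjusted p between 0.0682 and 0.98 without the block. DNA methylation machinery and readers had 11 of 19 positive, and Dnmt3a was its 1 called member. Its median (0.0454) and mean (0.0226) were positive where the test pointed downward, and imprinted genes had a median of 0.0272 and a mean of -0.0351, with Magel2 at -0.62 and Nnat at -0.43, neither of which passed. With the block, the imprinted gene Ndn rose (0.26, adjusted p = 0.0487 by edgeR), and 2 members, both higher, passed adjusted over the list alone. The ranges of Ndn overlapped, with 84.3 to 227.7 CPM in wild-type and 109.7 to 203.2 CPM in heterozygous animals. Ndn did not pass without the block (adjusted p = 0.978 by edgeR) or in the authors' DESeq comparison (0.098, adjusted p = 0.72). The median and the mean also differed in sign for the circadian, glucocorticoid, interferon and sex-linked lists, none of which was called.

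**Figure D3:**
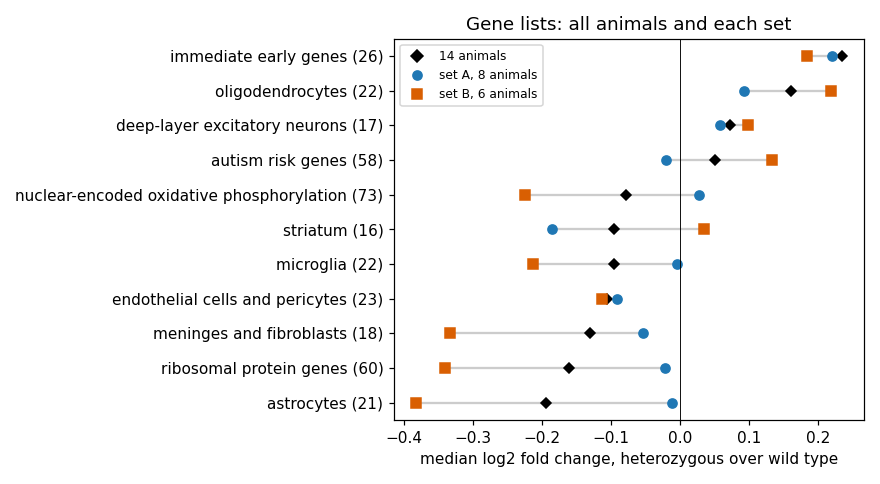
Median log2 fold change, heterozygous over wild type, of the 11 lists called by camera, with the number of tested genes in brackets, for the 14 animals (diamonds), set A (circles) and set B (squares). Astrocyte markers have medians of -0.012 in set A and -0.38 in set B, and immediate early genes 0.22 and 0.18.

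The genotype effect was then examined in each sex. In females, Dnmt3a had a log2 fold change of -0.56 (SE 0.103), Gpnmb 1.24, Trf 0.42, Cartpt -0.69 and Necab2 -0.49. In males, Dnmt3a had -0.57 (SE 0.119), Gpnmb 1.43, Myh7b 0.90, Ppm1m 0.49, Rab27a -0.65 and Dok1 -0.94, the last with a mean count under 20 and so uncertain. None of these passed the threshold by edgeR. In females 0 genes passed, with 521 at an unadjusted p under 0.05, and DESeq2 called 1, Dnmt3a (-0.55, adjusted p = 0.0155). In males 0 genes passed by edgeR, with 181 at an unadjusted p under 0.05, and DESeq2 also called 0. With the block, Aldh1a1 (-0.60), Dnmt3a (-0.56) and Sox21, a transcription factor gene (-0.50), fell in females and Dnmt3a (-0.57) fell in males. The difference between the sexes passed for 0 genes by edgeR, with 144 at an unadjusted p under 0.05 and 0 by DESeq2. Its smallest p values in each direction were those of Enpp6 (0.77, female minus male change), 1810029B16Rik (higher, with a mean count under 20 and so uncertain), Clec14a (0.79), Tchp (-0.88), Arl6ip4 (-0.48) and Mc4r (-1.20), with adjusted p of 1 by edgeR.

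Female and male genotype effects were compared across the 13815 genes. Pearson's r was 0.234 across genes, which are not independent replicates, and an exact permutation test within sex gave p = 0.26. With labels permuted within the title prefix as a block the exact p was 0.0625. Without 1 animal the correlation lay between 0.12 (wild type replicate 5) and 0.293 (wild type replicate 2). Within set A the correlation was 0.0225 (exact p = 0.889, where 0.11 is the smallest p possible).

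Long genes were compared because loss of methylation readers is known to move them in brain. The 2219 genes over 100 kb had a median log2 fold change 0.0147 above that of the 11383 shorter genes, and the exact permutation test within sex gave p = 0.529. The value went from 0.00103 without wild type replicate 4 to 0.0279 without heterozygous replicate 3, and was 0.0087 with the block. The difference was -0.00949 in set A (exact p = 0.833) and 0.0482 in set B (exact p = 0.167). The smallest p that the animals of either set allow is 0.056 in set A and 0.17 in set B, so neither could pass alone. Among long genes, Shroom3 had 0.45, Aldh1a1 -0.54 and Filip1 -0.51, and with the block all of these passed.

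Sex-linked genes checked the labels of sex. Xist, the RNA of the inactive X chromosome, was at 1067 ± 370 CPM in females (SD, n = 8) and 1.16 ± 0.475 CPM in males (SD, n = 6), with a log2 difference of 9.82 and an adjusted p of 2.35e-12 by edgeR. The Y-linked Ddx3y had 652 to 960 counts in each male and at most 3 in any female. The filter by genotype left out Y-linked genes because only 6 animals express them, and Xist was the 1 gene called. Filtering by sex called 8 genes, adding Ddx3y, Uty, Kdm5d, Eif2s3y, Kdm6a, Gadd45a and Tnfaip6. Kdm6a, an X-linked histone demethylase gene, was 0.43 higher in females, Gadd45a 0.75 and Tnfaip6 0.58. These did not pass with the filter by genotype (adjusted p = 0.0736, 0.0736 and 0.0802 by edgeR), where their rounded log2 differences were the same. Their adjusted p fell to 0.032, 0.032 and 0.038 by edgeR because the Y-linked genes, with very small p, entered the adjustment.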

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

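The glucocorticoid test was chosen after the result was seen, and the list tests of the difference between the sexes were not among the comparisons fixed beforehand.

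Camera on the difference between the female and the male genotype effect called 5 of the 32 lists, and none with an estimated correlation (smallest adjusted p = 0.96). Oligodendrocyte markers had a median log2 fold change of 0.25 in females and 0.0153 in males (adjusted p = 9.61e-06 for the difference). Immediate early genes had 0.0714 in females and 0.33 in males (adjusted p = 0.000959). Erythrocyte markers had 0.0585 in females and -0.37 in males (adjusted p = 0.000959). Endothelial and pericyte markers had -0.0637 in females and -0.12 in males, and the test called the difference with adjusted p = 0.029. Genes of the glucocorticoid response had -0.0566 in females and 0.0505 in males (adjusted p = 0.0372). No animal stood apart from its genotype group in library total, mitochondrial or ribosomal protein share, the genes named for genotype or the means of the called lists, over 50 groups examined by Dixon's criterion, where chance alone marks about 1 in 20.

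Immediate early genes were higher in heterozygotes in both sets, in 5 of 6 title prefixes. A difference between single animals irrespective of genotype could not be excluded, since exact permutation of the labels within the prefix gave p = 0.0521 for the list mean. A stress or glucocorticoid state at death could also raise these genes. The glucocorticoid list differed by 0.18 in set A (SD of relabellings 0.16) and by -0.12 in set B (SD of relabellings 0.098), both too close to that spread to decide, so it cannot be told apart from a genotype effect.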

How the results depend on the processing

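Terms for the set, each set alone, the filter by sex and DESeq2 with a set term were chosen after seeing the data. Genes changed by genotype numbered 2, and 11 with DESeq2, 11 with 1 surrogate variable, 56 with the title prefix as replicate block, 15 with a set term, 26 with DESeq2 and a set term, 0 in set A and 2304 in set B. Leaving out 1 animal gave 1 to 4, with 4 without wild type replicate 1 and 1 without wild type replicate 6 or 7 or any heterozygote but replicate 4. In females the count went from 0 to 1 with DESeq2, 3 with the block and 1 with a set term, and in males from 0 to 1 with the block. Genes changed by sex numbered 1, and 9 without a filter, 16 with DESeq2, 17 with a set term, 8 with the filter by sex and 1 to 12 without 1 animal. That count was 12 without wild type replicate 1, 6 without wild type replicate 3 or heterozygous replicate 3 or 4, 5 without wild type or heterozygous replicate 6 or 7, and 2 without wild type replicate 2. Without any of these females, 4 Y-linked genes pass the filter. Lists numbered 11, and 6 with 1 surrogate variable, 0 with an estimated correlation, 0 with fry and 6 to 14 without 1 animal (6 without wild type replicate 7). Dnmt3a was at -0.56 in set A, no longer past the threshold with 8 animals (adjusted p = 0.111 by edgeR). It kept its call in the other settings for both sexes together, with adjusted p up to 0.0374 by edgeR without 1 animal. In the main fit of each sex it did not pass by edgeR. The long-gene difference reversed to -0.00949 in set A, as did, fitted on those 8 animals alone, the tests of the autism risk (median -0.0196), oxidative phosphorylation (median 0.0269) and microglia lists (median -0.00227, the test upward). The cause was not tested beyond fewer animals. Other normalizations, filters, limma-voom, no sex term and a threshold of 0.1 kept the genotype count within 1.5 times. Apart from the genes counted above, the block added 2 lists to the 11 and changed no other call. Without 1 animal, agreement between the sexes lay between 0.12 and 0.293 and the long-gene difference between 0.00103 and 0.0279. Depth could limit genes of few counts such as Gpnmb, which was not tested.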

Other observations

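The tests in this part were chosen after the results were seen, except the counts of other splits of the animals. Within set B alone (3 heterozygous and 3 wild-type animals), edgeR called 2304 genes, 1233 higher and 1071 lower in heterozygotes, whereas within set A (4 and 4) it called 0, with 609 at an unadjusted p under 0.05. The sex term of these fits also separates the prefixes of set B. In set A each sex holds more than 1 prefix, so the prefixes are not separated and the 2 counts come from unlike fits. Camera called 14 lists in set B and 8 in set A, 3 of them in the same direction in both and 1, the clustered protocadherins, in opposite directions. Those cell adhesion genes had a median log2 fold change of -0.0772 in set A and 0.21 in set B, and camera on the difference gave adjusted p = 1.52e-07 (adjusted p = 0.249 with an estimated correlation). No list was called in either set with an estimated correlation (smallest adjusted p = 0.45 in set A and 0.39 in set B). Voltage-gated channels had -0.0305 in set A and 0.17 in set B. The test of single genes for a difference between the sets called 0 by edgeR, with 2036 at an unadjusted p under 0.05.

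An equal effect in both sets, called in set B for its smaller spread, is argued against. The 2298 genes called in set B that were tested in all animals changed by a mean of 0.324 in set B and by 0.0095 in set A in the same direction (SD over relabellings of set A 0.0332), and 49.5% kept their sign in set A. An axis of tissue or RNA state on which animals of 1 genotype also differ stays open. The set B difference correlated across genes at 0.23 with the first component of set A after genotype and sex. As large a correlation came from 4 of 12 relabellings of set B, where the smallest share possible is 0.17. So the 2 cannot be told apart with 6 animals. On the first component of all animals, set B heterozygotes lay nearer to set A than wild-type animals of their prefix. The values were 2.06 against 10.97 in prefix 119, and 15.79 and 11.11 against 33.12 and 30.9 in prefix 141. Prefixes of set A went both ways. That component was computed from these same animals, so it does not decide. The 10 splits of set B are too few for a share under 0.05, and 1, the real one, gave as many genes, with 1 gene the highest of the others.

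The rise from 2 to 56 calls with the title prefix as block may come from level differences between the sets that widen the spread without it. A term for the set alone raised the calls to 15, and the median residual SD of log2 CPM fell from 0.189 with sex to 0.147 with set and sex and 0.135 with the prefix. What adds the calls from 15 to 56 stays open. Of the 96 splits that part every prefix, 3 gave as many as 56 genes, the real one included, a share under 0.05. The count does not exclude chance for these genes, since 2 splits with other labels gave more, 230 and 145 genes. Both keep the real parting of prefixes 048, 119 and 141 and exchange the genotypes in 046 and 139, the second in 047 too. This points to a structure of these animals.

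Other splits were also counted for the remaining comparisons. For genotype with sex as a term, 3 of 100 sex-balanced splits gave as many as the 2 genes, the real one included, a share under 0.05. Of the 2 genes, Dnmt3a is the targeted one, so the count does not exclude chance for Gpnmb. Another split gave 720, and that split held 5 of the 6 animals of set B in 1 group. For lists, 39 of 100 splits gave as many as 11, with 18 the highest of the others, and with the block 22 of 96 gave as many as 13, with 17 the highest, so chance is not excluded for the number of lists. For the 0 genes in females every one of the 35 splits gave as many, as any split must where the real count is 0. This and the other real counts of 0 below therefore do not test chance. The highest of the others in females, 3811 genes, parted the females by set, and the block gave 3 genes in females. For the 0 genes of the difference between sexes all 100 splits gave as many, with 3941 the highest, a split that placed the 4 females of set B together. For the 0 genes in set A all 34 splits that could be fitted did, with 81 the highest. The 10 splits of the males are too few for a share under 0.05, with 0 genes in the real one, 0 as the highest of the others and all 10 as large. For the 1 gene called by sex, 4 of 100 splits gave as many, the real one included, a share under 0.05. That gene is Xist, which marks the sex itself, so the count does not test chance for other genes. The highest of the others gave 3357 with 1 of the 6 set B animals in the group of 8. These large counts point to a structure of the animals. The 3811 and 3941 genes came from the only splits of their kind that kept the set B females together. Of the 3 splits by sex with 1 of the 6 set B animals in the group of 8, the others gave 3076 and 0 genes, and the 1 split with all 6 there gave 772, so these counts went largely with the set. The set alone does not give the 720, since the 9 other genotype splits that parted set B into 5 and 1 gave 0. A term for the set gave 17 genes by sex.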
